A study of Mus musculus with 12 samples.

How the data were processed

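Total RNA of mouse meninges, stored in RNAlater and extracted with a column kit, was made into stranded total RNA libraries, per the labels' protocols. There were 12 libraries, 3 in each of 4 groups. Per the submitters' processing notes, the tools were CASAVA, FastQC, Trim Galore, HISAT2 and featureCounts with the genome build mm10. Their versions, the annotation and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of overlapping antisense genes cannot be told apart.

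The authors deposited a table of raw counts per gene, 47747 gene symbols in 12 columns of whole numbers, and a second table of normalized values (unit signal). The normalized signal values the authors deposited equal the counts divided by 1 factor per library, and 2099 genes with a single count in all are left out of that table. The raw counts were used for all main results. Columns were matched to samples by the leading number in the sample titles, and no column of the tables was left unmapped. Of the symbols, 45251 matched GENCODE M21, which is on the same build as mm10 and gave the coordinates and exon lengths.

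Genes were kept with edgeR's filterByExpr by group, which left 20016, and scaled by TMM factors. All 12 libraries were fitted in 1 model with a mean per group (8 residual degrees of freedom) and tested with edgeR 4.0.16 (glmQLFit, glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. Comparisons were GF, Donor3 and Donor7 against each other and against SPF, GF against the mean of the other groups, and a test of any difference.

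Before the data were examined, 59 gene lists (immune cells, stromal cells, neighbouring tissues, programmes and a check of sex-linked genes), the design, the alternatives and the rule for named genes were fixed. The 55 lists with at least 4 tested members, other than the sex check, were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and again with an estimated one. The rule named up to 12 genes per direction in each main comparison and 5 in each other one, past the threshold, with a mean of at least 1 CPM and with all libraries of one group above all of the other. Where no gene passed it named the 3 with the smallest p per direction. It added up to 4 genes of each list past the threshold, a panel of 10 immune genes and 10 genes of the test of any difference. Unnamed gene models and clone names were counted, not named. The text describes a list by its genes only where its unadjusted p with an estimated correlation was also under 0.05, apart from lists of bone, marrow and neighbouring tissue given beside others to show what moved with them: mature neutrophils in GF against SPF, choroid plexus in Donor3 against GF, bone-forming cells, mature neutrophils and granulocyte precursors in Donor7 against GF, and astrocytes in Donor7 against Donor3. That condition and these exceptions were set after the data were seen. Not every gene the rule allows is printed, and the results of some genes are not reported here.

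The fit was tested on simulated counts with 50 genes per fold size changed in GF. For GF against SPF it called 28% of genes changed 1.5-fold, 68% of those changed 2-fold, 94% at 4-fold and 100% at 8-fold, with 7 false calls. For Donor3 against GF it called 18%, 64%, 92% and 98%, with 6 false calls. The simulation gave each gene 1 dispersion for all libraries and let genes vary independently, so no library stood apart in composition. Pairs of real libraries differed by a chi-square per degree of freedom of 138 to 196 within GF and 22.8 to 70.5 within the other groups. These rates may therefore be too high for the GF comparisons.

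Alternatives fixed in advance were RLE scaling, no filter, the replicate number as a block, only the groups compared, DESeq2 1.42.0, limma with voom sample weights, limma on log2 of the deposited normalized values plus 1, an estimated correlation, and each library left out in turn. Added after seeing the data were an exact two-sided permutation test of list levels (mean log2 CPM of a list's genes) in 1 group against the other 9 libraries, GF replicates 2 and 3 left out together, the mean log2 CPM of the choroid plexus list as a covariate, and removal of each library's trend on exon length. Sex was not modelled because all libraries had 1 pattern of sex-linked genes. Figures were drawn with matplotlib 3.10.9. Also added then were linear models of list levels on group, fitted with and without the choroid plexus level or the mean level of the bone-forming cell, mature neutrophil and granulocyte precursor lists as a covariate. Those 3 lists held 26 tested genes, of which 0 were in the T cell, monocyte, macrophage, complement, interferon or immunoglobulin constant lists.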

Results

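RNA was measured in the meninges, the membranes around the brain and spinal cord, of mice that differed in their microbiome. The labels give 4 groups of 3 libraries each: specific pathogen free mice (SPF), germ-free mice (GF), which carry no microbes, and 2 groups named for a donor (Donor3 and Donor7). What the donors were is not stated in the labels, nor are the sex, age or strain of the mice. Total counts per library ran from 25160236 to 34224098 in SPF, from 7026082 to 32741307 in GF, from 21194609 to 29417308 in Donor3 and from 29008897 to 37370264 in Donor7. The labels do not say whether the 3 libraries of a group came from separate mice, so the p-values measure the spread between these libraries. Values per gene are CPM, counts scaled to a common library size, given as the mean over the 3 libraries of a group, with ± SD for some genes. Values printed without an SD are means alone and do not show the spread between libraries.

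Some libraries stood apart in their composition. GF replicate 2 had the lowest total and 4.14% of its counts were on the 18S ribosomal RNA gene Rn18s, against at most 0.334% in any other library. The 7SL RNA genes Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, took 13.3% of the counts of GF replicate 2 and 16.2% of those of GF replicate 3, against 7.95% to 12.3% in the other 10 libraries. Mitochondrially encoded genes took 6.96% ± 0.12 of the counts in SPF, 8.04% ± 2.12 in GF, 10.2% ± 1.7 in Donor3 and 11.1% ± 0.3 in Donor7. Markers of the choroid plexus, the tissue that secretes cerebrospinal fluid, also varied: the mean log2 CPM of 13 such genes, centred on the 12 libraries, was -2.75 in SPF replicate 1, -1.89 in SPF replicate 3 and -2.31 in Donor3 replicate 3, against -0.05 to 1.51 in the other 9. All 12 libraries held Xist at 413 CPM or more and at most 1 count on 4 genes of the Y chromosome.

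Over all 4 groups, 739 of 20016 genes differed between any of the groups (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05). The 10 nameable genes with the smallest p were Mid1, Nnt, Gclc, Crb1, Dnajb9, Adam19, Hist1h4h, Creld2, Ifit3 and Rpl26, with adjusted p from 0.000846 to 0.0186 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Mid1 encodes a ubiquitin ligase that binds microtubules, Nnt a mitochondrial enzyme that makes NADPH, Gclc the catalytic part of the first enzyme of glutathione synthesis, and Ifit3 an interferon-induced antiviral protein. Dnajb9 and Creld2 are induced by unfolded protein in the endoplasmic reticulum. The count was 7 without SPF replicate 1, 7 without SPF replicate 3, 1966 without GF replicate 1 and 249 without GF replicate 2. It was 20, 346 and 204 without Donor3 replicates 1, 2 and 3, 18, 140 and 44 without Donor7 replicates 1, 2 and 3, and 22 with the choroid plexus level as a covariate, an alternative chosen after seeing the data.

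The comparison of GF with SPF asks how meninges of mice with no microbes differ from those of specific pathogen free mice. Strain is not given in the labels and may also differ between these groups. Nnt was lower in GF, at 28.0 ± 3.1 CPM against 56.4 ± 7.8 in SPF, a log2 fold change of -1.02 (SE 0.11). Mid1 was lower too, at 19.9 ± 4.8 CPM against 59.5 ± 7.7, with a log2 fold change of -1.61 (SE 0.16). Crb1, which encodes a protein of cell polarity in the retina, was higher in GF, at 18.2 ± 2.7 CPM against 4.81 ± 1.22. Vopp1 stood at 79.2 ± 11.0 CPM in GF and 40.6 ± 5.0 in SPF. In these 4 genes GF, Donor3 and Donor7 differed by at most 0.27 (log2, Mid1). SPF lay at least 0.895 from each of these groups (log2, Vopp1). The differences in these genes therefore cannot be credited to the absence of microbes. Ikzf3, a transcription factor of lymphocytes, was lower in GF, at 1.25 ± 0.14 CPM against 3.77 ± 0.97. Upp1 and Hist1h4h were higher, with log2 fold changes of 1.16 and 0.70, and Col6a5, a collagen gene, was lower, with a log2 fold change of -0.87. In all, 14 genes passed, 7 higher and 7 lower in GF, with adjusted p for the named genes between 0.00675 and 0.0407 (edgeR quasi-likelihood test, Benjamini-Hochberg). In GENCODE M21 coordinates on mm10, Nnt lies on chromosome 13 from 119335448 to 119408997, Crb1 on chromosome 1 from 139197056 to 139377100, Mid1 on chromosome X from 169685199 to 170005736 and Vopp1 on chromosome 6 from 57727807 to 57825159, each given as the whole gene. Mid1 shares sequence with copies elsewhere, so its counts are uncertain. The test called 3 genes without GF replicate 3, 4 without SPF replicate 1, 8 without SPF replicate 3 or GF replicate 1, 2 with only these groups fitted and 2 with the choroid plexus level as a covariate. With 1 library left out Nnt and Mid1 passed in each of the 6 fits, while Upp1 and Ikzf3 passed in none.

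**Figure D1:**
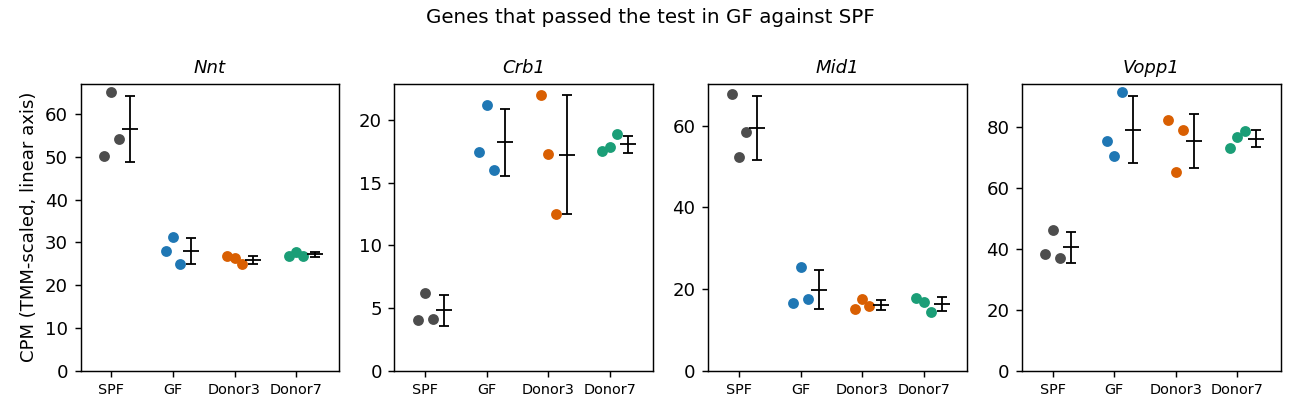
CPM (linear axis) of Nnt, Crb1, Mid1 and Vopp1, with 1 point per library and, beside each group, a bar at the mean with whiskers of 1 SD over 3 libraries. Nnt averaged 56.4 CPM in SPF and 28.0 in GF, and Donor3 and Donor7 stood near the GF level in each of the 4 genes.

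Among lists of genes, 34 of 55 passed in GF against SPF, 12 higher and 22 lower (limma camera with a preset correlation of 0.01, Benjamini-Hochberg adjusted p under 0.05), but none with an estimated correlation, the smallest adjusted p being 0.234 by camera. In the comparisons that follow, the adjusted p given in parentheses after a list is that by camera with an estimated correlation. Genes of immune cells stood lower in GF than in SPF, beside the low depth of GF replicate 2 and the larger 7SL share of GF replicates 2 and 3. All 17 tested T cell genes had negative fold changes, with a median log2 fold change of -1.10 (adjusted p = 0.234). Cd4, the coreceptor of helper T cells, stood at 5.46 CPM in GF and 9.68 in SPF, and Lat, an adaptor of T cell signalling, at 1.12 and 2.65. Of these genes 13 passed when adjusted over the list alone and 0 over all genes tested. All 12 tested genes of immunoglobulin constant regions and the J chain had negative fold changes, with a median of -1.28 (adjusted p = 0.234), or -1.18 with 1 gene that no GF or no SPF library held set to its limit (3 counts over the group). Of these, 1 passed when adjusted over the list alone and 0 over all genes. Igha, which encodes the heavy chain of IgA, had 14, 0 and 23 counts in the 3 GF libraries. It stood at 0.497 ± 0.545 CPM in GF and 15 ± 7.3 in SPF, and did not pass (log2 fold change -4.62, SE 0.78, adjusted p = 0.067, edgeR quasi-likelihood with Benjamini-Hochberg). B cell genes (11 of 11 lower, median -0.34, 1 past when adjusted over the list alone, 0 over all genes, adjusted p = 0.234), monocyte genes (7 of 8 lower, median -0.68, 4 and 0, adjusted p = 0.234) and type I interferon genes (26 of 27 lower, median -0.26, 9 and 0, adjusted p = 0.234) passed with the preset correlation too. In B cell genes SPF stood above all other groups, with centred log2 levels of 0.29 in SPF, -0.21 in GF, -0.10 in Donor3 and 0.02 in Donor7. Genes of bone marrow and blood were low in GF replicates 2 and 3: mature neutrophil genes, 6 of 7 lower with a median of -0.66 (0 past either way, adjusted p = 0.445), had centred log2 levels of 0.05, -1.07 and -1.05 in GF replicates 1, 2 and 3. The levels were 0.29, -1.03 and -1.40 for granulocyte precursors, -0.23, -1.10 and -0.59 for erythroid cells and -0.18, -0.58 and -0.99 for bone-forming cells. Among the interferon genes Oasl2 stood at 28.7 CPM in GF and 39.0 in SPF, and Oas2 at 7.11 and 11.6. Of the single immune genes fixed beforehand, Cd3e, Mrc1, H2-Aa, S100a8, Jchain, Ighm, Igkc and Mzb1 did not pass, with log2 fold changes from -1.35 in Igkc to -0.14 in H2-Aa.

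Other lists were higher in GF than in SPF. All 13 choroid plexus genes, whose level was low in SPF replicates 1 and 3, had positive fold changes, with a median of 2.44, and Kcnj13 stood at 34.2 CPM in GF and 6.83 in SPF (10 past when adjusted over the list alone, 0 over all genes, adjusted p = 0.234). Among genes of barrier junctions 13 of 15 were higher, with a median of 0.31, and the tight junction gene Cldn5 stood at 54.6 CPM in GF and 29.9 in SPF (5 and 0 past, adjusted p = 0.234). Of 80 genes for cytosolic ribosomal proteins 79 were higher, with a median of 0.31 (66 past when adjusted over the list alone, 0 over all genes, adjusted p = 0.234), and all 13 mitochondrially encoded genes were higher, with a median of 0.43 (9 and 0, adjusted p = 0.234), while the mitochondrial share of counts was 8.04% in GF and 6.96% in SPF. Fatty acid oxidation genes were higher in 12 of 12, with a median of 0.22 and Cpt1a, which carries fatty acids into mitochondria, at 95.7 CPM against 72.3 (2 and 0, adjusted p = 0.234). In these last 3 lists SPF was the lowest group. Centred log2 levels in SPF, GF, Donor3 and Donor7 were -0.32, -0.01, 0.22 and 0.12 for ribosomal proteins. They were -0.46, 0.03, 0.17 and 0.26 for mitochondrially encoded genes and -0.23, -0.01, 0.17 and 0.07 for fatty acid oxidation. The differences in these 3 lists therefore cannot be credited to the absence of microbes. All 12 bone-forming cell genes were lower, with a median of -0.40 (5 and 0, adjusted p = 0.243), and Bglap and its near-identical neighbour Bglap2, which share reads, stood at 135 and 133 CPM in GF and 380 and 373 in SPF. Without GF replicates 2 and 3 together, chosen after seeing the data, 20 lists passed.

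**Figure D2:**
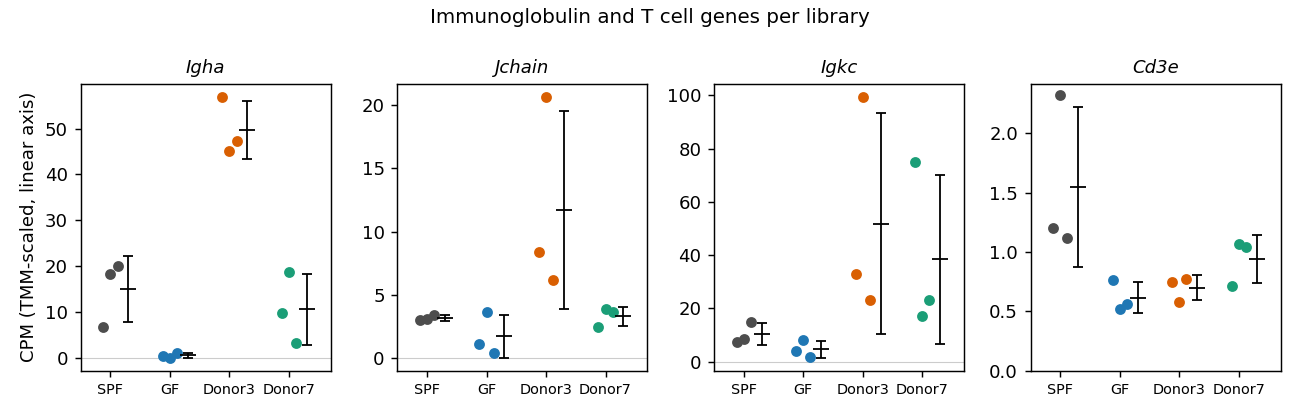
CPM (linear axis) of Igha, Jchain, Igkc and Cd3e, with 1 point per library and, beside each group, a bar at the mean with whiskers of 1 SD over 3 libraries. Igha averaged 0.497 CPM in GF, 15 in SPF, 49.8 in Donor3 and 10.5 in Donor7.

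Donor3 against GF compares mice whose microbiome status was given as Donor3 with germ-free mice. Igha stood at 49.8 ± 6.3 CPM in Donor3 and 0.497 ± 0.545 in GF, a log2 fold change of 6.35 (SE 0.79). Igkc, the kappa light chain, stood at 51.8 ± 41.6 CPM against 4.67 ± 3.18, and Jchain, which joins secreted IgA and IgM, at 11.7 ± 7.8 against 1.76 ± 1.70. No gene passed in this comparison by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the smallest adjusted p being 0.0791, that of Igha. At an unadjusted p under 0.05 there were 2993 genes. DESeq2 called 325, and limma, either with voom sample weights or on the deposited normalized values, called 0. Apart from Igha, the genes with the smallest p were Xdh and Smad9 on the higher side, with log2 fold changes of 0.59 and 0.53, and Adamts1, Nes and Mapkapk3 on the lower side, with -0.60, -0.71 and -0.59. The same test called 147 genes without GF replicate 1 and 3 without Donor3 replicate 2.

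Among lists, 31 of 55 passed in Donor3 against GF, 29 higher and 2 lower (camera, preset correlation, Benjamini-Hochberg), and with an estimated correlation 1 passed, that of endoplasmic reticulum stress, at an adjusted p of 0.0199 by camera. With the depth and 7SL share of the GF libraries as given above, 11 of 12 genes of immunoglobulin constant regions and the J chain were higher in Donor3 than in GF, with a median log2 fold change of 2.72 (adjusted p = 0.0899 with an estimated correlation), and 5 passed when adjusted over the list alone and 0 over all genes. Immunoglobulin variable segments were higher in 23 of 23, with a median of 3.89, or 3.40 with 3 segments at 0 in a whole group set to their limit (10 and 0 past, adjusted p = 0.145). Reads of these segments can be shared between near-identical copies. Genes of border macrophages were higher in 20 of 20, with a median of 0.61 (14 and 0 past, adjusted p = 0.149): the haemoglobin scavenger receptor Cd163 stood at 74.2 CPM in Donor3 and 39.2 in GF, and Lyve1 at 21.4 and 7.97. Complement genes were higher in 14 of 14, with a median of 0.48 (8 and 0, adjusted p = 0.145): Cfp, which encodes properdin, stood at 33.0 CPM against 18.0. Monocyte genes (8 of 8, median 0.57, 2 and 0 past, adjusted p = 0.169), mast cell genes (11 of 12, median 0.74, 7 and 0, adjusted p = 0.169) and plasma cell genes other than immunoglobulins (9 of 11, median 0.37, 2 and 0, adjusted p = 0.169) were higher as well. Tpsb2, a mast cell tryptase, stood at 33.4 CPM against 19.6, and Xbp1, a transcription factor of secretory cells, at 114 against 86.3. Secretory cells are not only plasma cells, and endoplasmic reticulum stress genes were higher too, so Xbp1 alone does not show more plasma cells. Mzb1, of the immune panel, had 8, 16 and 6 raw counts in the Donor3 libraries and 7, 0 and 6 in the GF libraries. Marrow genes rose beside these lists. The centred log2 level of mature neutrophil genes was 0.28 ± 0.56 in Donor3 and -0.69 ± 0.64 in GF. That of granulocyte precursor genes was 0.27 ± 0.53 and -0.72 ± 0.89.

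All 12 genes of endoplasmic reticulum stress were higher in Donor3 than in GF, with a median log2 fold change of 0.51, and 9 passed when adjusted over the list alone and 0 over all genes. Hspa5, the main chaperone of the endoplasmic reticulum, stood at 613 CPM in Donor3 and 383 in GF, and Manf, a secreted stress protein, at 70.2 and 41.7. All 11 glucocorticoid targets were higher, with a median of 0.89 (8 and 0 past, adjusted p = 0.169), and Fkbp5, a cochaperone of the glucocorticoid receptor, stood at 156 CPM against 53.6. Heat shock genes were higher in 8 of 8, with a median of 0.28 (3 and 0, adjusted p = 0.169), as were 4 of 5 targets of the aryl hydrocarbon receptor, with a median of 0.51 (2 and 0, adjusted p = 0.169). Lists of neighbouring tissue went both ways: 12 of 13 choroid plexus genes were lower, with a median of -0.99 (0 past either way, adjusted p = 0.556), while 14 of 16 neuronal genes were higher, with a median of 0.37 (0 past either way, adjusted p = 0.176), and 11 of 12 genes of bone-forming cells, with a median of 0.97 (1 and 0, adjusted p = 0.176). Without GF replicates 2 and 3, 18 lists passed.

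Donor7 against GF makes the same comparison for the other donor group. The interferon-induced genes Ifit3 and Ifit1 had the smallest p: Ifit3 stood at 86.5 ± 10.8 CPM in Donor7 and 43.2 ± 6.8 in GF, and Ifit1 at 31.0 ± 4.3 and 13.5 ± 2.4. Their log2 fold changes were 0.99 (SE 0.13) and 1.20 (SE 0.16). Neither passed, at an adjusted p of 0.0814 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Grin2b, a glutamate receptor gene of neurons, stood at 9.45 ± 2.98 CPM against 2.10 ± 0.92, and Syvn1, Col7a1 and Meg3 had log2 fold changes of -0.48, -1.03 and -0.55. Igha stood at 10.5 ± 7.8 CPM, a log2 fold change of 4.10 (SE 0.78). No gene passed by edgeR. At an unadjusted p under 0.05 there were 3663 genes, DESeq2 called 478, and limma with voom weights or on the normalized values called 0. The same test called 875 genes without GF replicate 1, 1 without GF replicate 2 and 2 without Donor7 replicate 2.

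Among lists, 26 of 55 passed in Donor7 against GF, all higher (camera, preset correlation, Benjamini-Hochberg), and none with an estimated correlation, the smallest adjusted p being 0.12 by camera. With the depth and 7SL share of the GF libraries as given above, genes of bone and marrow were higher beside the immune lists: 9 of 12 bone-forming cell genes (median 0.75, adjusted p = 0.423), 7 of 7 mature neutrophil genes (median 0.82, adjusted p = 0.423) and 7 of 7 granulocyte precursor genes (median 0.85, adjusted p = 0.437) were higher in Donor7, with 0 genes past either way. All 27 type I interferon genes were higher in Donor7 than in GF, with a median log2 fold change of 0.51 (adjusted p = 0.12 with an estimated correlation), and 19 passed when adjusted over the list alone and 0 over all genes. Complement genes were higher in 14 of 14, with a median of 0.53 (11 and 0 past, adjusted p = 0.261). Border macrophage genes were higher in 19 of 20, with a median of 0.56 (12 and 0, adjusted p = 0.383), and C1qb stood at 108 CPM against 71.5. Monocyte genes were higher in 8 of 8, with a median of 0.75 (3 and 0, adjusted p = 0.261), and immunoglobulin constant regions in 11 of 12, with a median of 1.63 (3 and 0, adjusted p = 0.296). That median was the same with 1 gene at its limit. Ighg3 had no count in any GF library and a mean of 36.7 CPM in Donor7. Neuronal genes were higher in 13 of 16, with a median of 0.53 (7 and 0, adjusted p = 0.217), and Gad1, which makes the transmitter GABA, stood at 18.3 CPM against 1.67. The centred log2 level of astrocyte genes, of neighbouring brain tissue, was 0.61 ± 0.54 in Donor7 and -0.27 ± 0.32 in GF. Without GF replicates 2 and 3, 18 lists passed.

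**Figure D3:**
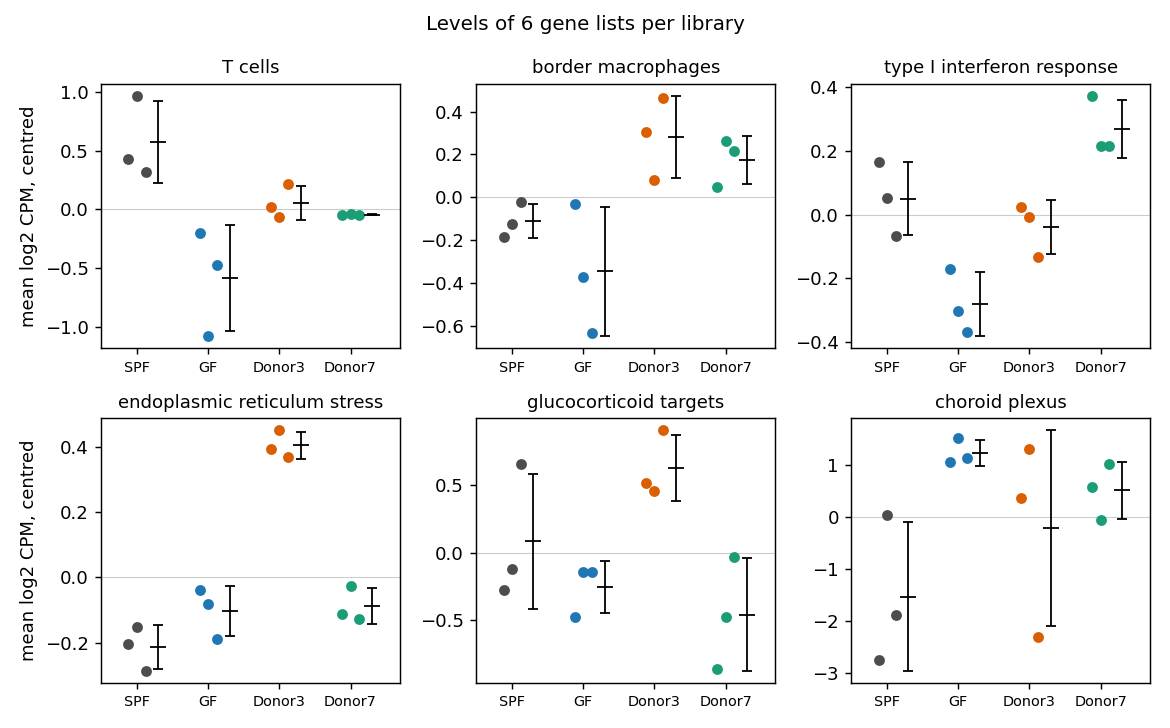
Mean log2 CPM of the genes of 6 lists, centred on the 12 libraries, with 1 point per library and, beside each group, a bar at the mean with whiskers of 1 SD over 3 libraries. The endoplasmic reticulum stress level of the Donor3 libraries averaged 0.41, above all others, and the choroid plexus level was -2.75 in SPF replicate 1.

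The comparison of Donor7 with Donor3 tests whether the 2 donor groups differed. Gclc fell from 65.8 ± 4.5 CPM in Donor3 to 30.7 ± 4.2 in Donor7, a log2 fold change of -1.10 (SE 0.11). Creld2 fell from 36.1 ± 4.1 to 19.8 ± 0.5 CPM, a log2 fold change of -0.87 (SE 0.10). These were the 2 genes that passed, with adjusted p of 0.00967 and 0.0338 (edgeR quasi-likelihood test, Benjamini-Hochberg). Gclc lies on chromosome 9 from 77754535 to 77794485 and Creld2 on chromosome 15 from 88819646 to 88826683. Gclc passed with each of the 6 libraries left out in turn, but Creld2 passed only without Donor3 replicate 3, where 11 genes passed; 1 gene passed without Donor3 replicate 2 and 1 without Donor7 replicate 1. With only these groups fitted neither passed. Igha stood at 10.5 ± 7.8 CPM in Donor7 and 49.8 ± 6.3 in Donor3 and did not pass.

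Among lists, 19 of 55 passed in Donor7 against Donor3, 9 higher and 10 lower (camera, preset correlation, Benjamini-Hochberg), and with an estimated correlation 1 passed, endoplasmic reticulum stress, at an adjusted p of 0.0090 by camera. Endoplasmic reticulum stress genes were lower in Donor7 in 11 of 12, with a median log2 fold change of -0.62, and 9 passed when adjusted over the list alone and 1, Creld2, over all genes. Hspa5 stood at 382 CPM in Donor7 and 613 in Donor3, and Herpud1, a part of the degradation of misfolded proteins, at 61.4 and 101. All 11 glucocorticoid targets were lower, with a median of -0.65 (8 and 0 past, adjusted p = 0.18 with an estimated correlation). Zbtb16 stood at 15 CPM against 128, Fkbp5 at 39.4 against 156 and Tsc22d3 at 242 against 668. Heat shock genes were lower in 8 of 8, with a median of -0.32 (3 and 0, adjusted p = 0.261). Type I interferon genes were higher in Donor7 in 23 of 27, with a median of 0.30 (8 and 0, adjusted p = 0.18), and Ifit3 stood at 86.5 CPM against 47.9. Leptomeningeal cell genes were higher in 12 of 12, with a median of 0.63 (5 and 0, adjusted p = 0.274), and Slc22a6, an organic anion transporter, stood at 50.9 CPM against 24.5. Astrocyte genes, of neighbouring brain tissue, were higher in 8 of 9, with a median of 0.62 (0 past either way, adjusted p = 0.444). The levels of the leptomeningeal and astrocyte lists overlapped between the 2 donor groups. On the centred log2 scale Donor3 replicate 3 stood at 0.24 and 0.58, above Donor7 replicate 2 at 0.05 and 0.06. Immunoglobulin variable segments were lower in 14 of 23, with a median of -1.55 (5 and 0, adjusted p = 0.333). The list for type 3 lymphocytes passed with 3 genes higher and 3 lower and a median of -0.02 (adjusted p = 0.274), and its one gene that passed when adjusted over the list alone (0 over all genes) was Zbtb16, which also stands in the glucocorticoid list.

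Against SPF, both donor groups differed in many genes. Strain, not given in the labels, may differ from SPF here too, so these counts cannot be credited to the microbiome alone. In Donor3 1526 genes passed, 688 higher and 838 lower, and in Donor7 1514 passed, 637 higher and 877 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Crb1 was higher in both, at 17.2 ± 4.7 CPM in Donor3 and 18.1 ± 0.7 in Donor7 against 4.81 ± 1.22 in SPF. Pydc3, an interferon-induced gene of a family with near-identical copies, was higher in both, at 2.58 ± 0.27 and 2.66 ± 0.30 against 0.53 ± 0.25 CPM. In Donor3 the small noncoding RNAs Rny1, Rny3, Snord21 and Snord49b were lower, with Rny3 at 2.10 ± 1.30 CPM against 34.9 ± 3.7 in SPF. Grm6, Ighj4 and Tal2 also passed, with log2 fold changes of -2.37, 2.55 and 1.89, and Igkv4-55, which no SPF library held, passed at 3.32 ± 4.16 CPM in Donor3. In Donor7 Mid1 was lower, at 16.4 ± 1.7 CPM against 59.5 ± 7.7, and Zbtb16 at 15 ± 8.1 against 85.7 ± 51.4. The ribosomal genes Rps13-ps2 and Rps3a2, whose reads can belong to the parent genes, had log2 fold changes of 2.84 and 2.44, and Synpr, A3galt2, Adam4 and Wdr46-ps had 2.07, -2.15, -1.72 and -1.67. The counts depended on most single libraries. In Donor3 74 genes passed without SPF replicate 1, 276 without SPF replicate 3, and 110, 861 and 318 without Donor3 replicates 1, 2 and 3, and in Donor7 10 passed without SPF replicate 1, 13 without SPF replicate 3, and 46, 23 and 11 without Donor7 replicates 1, 2 and 3. SPF replicates 1 and 3 had low choroid plexus levels, and with that level as a covariate 414 genes passed in Donor3, 269 higher and 145 lower, and 84 in Donor7, 62 higher and 22 lower, so the larger side turned from lower to higher. With each library's length trend removed 926 passed in Donor3, 290 higher and 636 lower, and 1080 in Donor7, 325 higher and 755 lower.

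Among lists, 15 passed in Donor3 against SPF, 14 higher and 1 lower, and 21 in Donor7, 17 higher and 4 lower (camera, preset correlation), and with an estimated correlation 1 passed in Donor3, endoplasmic reticulum stress at an adjusted p of 0.0291, and 0 in Donor7. Ribosomal protein genes were higher than in SPF in 80 of 80 for both donor groups, with median log2 fold changes of 0.53 in Donor3 and 0.42 in Donor7, and 73 and 65 of them passed over all genes (79 and 77 when adjusted over the list alone). With an estimated correlation the adjusted camera p was 0.189 and 0.413. In Donor3 and Donor7, 61 and 7 of these genes passed over all genes with the choroid plexus level as a covariate. With the length trend removed 50 and 33 passed. Mitochondrially encoded genes were higher in 13 of 13 in both, with medians of 0.61 and 0.72 (8 and 9 past over all genes, 10 and 11 when adjusted over the list alone, adjusted p = 0.332 and 0.413), as the share of mitochondrial counts was. Fatty acid oxidation genes were higher in 12 of 12 in Donor3 and 11 of 12 in Donor7, with medians of 0.27 and 0.33 (3 and 3 past over all genes, 8 and 7 adjusted over the list alone, adjusted p = 0.328 and 0.466). In Donor3, endoplasmic reticulum stress genes were higher in 12 of 12, with a median of 0.65 (8 past over all genes, 10 adjusted over the list alone). Histone genes (66 of 68, median 0.62, 15 over all genes, 23 adjusted over the list alone, adjusted p = 0.328) and heat shock genes (8 of 8, median 0.45, 3 and 5, adjusted p = 0.328) were higher in Donor3 too. In Donor7, junction genes were higher in 11 of 15, with a median of 0.31 (3 and 8, adjusted p = 0.413), and the type 3 lymphocyte list was lower in 4 of 6, with a median of -0.34 (2 and 2, adjusted p = 0.413). Zbtb16, which also stands in the glucocorticoid list, was among the genes of the type 3 lymphocyte list that passed.

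GF was also set against the mean of the other 3 groups. Igha stood at 0.497 ± 0.545 CPM in GF and 25.1 ± 19.6 over the other 9 libraries, and did not pass (log2 fold change -5.02, SE 0.74, adjusted p = 0.226, edgeR quasi-likelihood with Benjamini-Hochberg). The one gene that passed was Gm5453, an unnamed gene model outside the rule for named genes and chosen after its values were seen, which was higher in GF by a log2 fold change of 2.67 (SE 0.29, adjusted p = 0.0281 by edgeR quasi-likelihood with Benjamini-Hochberg). At an unadjusted p under 0.05 there were 2674 genes, and DESeq2 called 102. No gene passed by edgeR without SPF replicate 1, 2 or 3, GF replicate 3, Donor3 replicate 1 or 3, or Donor7 replicate 1, while 22 passed without GF replicate 1 and 2 without Donor3 replicate 2 or Donor7 replicate 3. Nes, Upp1, Xdh and Ly9 had log2 fold changes of 0.56, 0.74, -0.44 and -0.91 and did not pass, and neither did the ribosomal pseudogene Rps12-ps24.

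Among lists, 33 of 55 passed in GF against the mean of the others, 5 higher and 28 lower (camera, preset correlation), and none with an estimated correlation, the smallest adjusted p being 0.125 by camera. GF replicate 2 had the lowest depth, and GF replicates 2 and 3 had the larger 7SL shares and low levels of mature neutrophil (-1.07 and -1.05) and granulocyte precursor genes (-1.03 and -1.40), against 0.05 and 0.29 in GF replicate 1. Type I interferon genes were lower in GF in 27 of 27, with a median of -0.36 (17 past when adjusted over the list alone, 0 over all genes, adjusted p = 0.125 with an estimated correlation), complement genes in 14 of 14, with a median of -0.41 (9 and 0, adjusted p = 0.128), and monocyte genes in 8 of 8, with a median of -0.69 (4 and 0, adjusted p = 0.125). T cell genes were lower in 17 of 17 (median -0.65, 1 and 0, adjusted p = 0.218) and macrophage genes in 19 of 20 (median -0.48, 13 and 0, adjusted p = 0.172). Centred log2 levels in GF replicates 1, 2 and 3 were -0.03, -0.37 and -0.63 for macrophage genes and -0.12, -0.33 and -0.49 for complement genes. In SPF replicates 1, 2 and 3 they were -0.18, -0.13 and -0.02, and -0.14, -0.03 and -0.09. GF replicate 1 thus lay within the range of SPF in both lists. Immunoglobulin constant regions were lower in 12 of 12 (median -1.82, 3 and 0, adjusted p = 0.125), bone-forming cell genes in 12 of 12 (median -0.91, 3 and 0, adjusted p = 0.172), neuronal genes in 13 of 16 (median -0.37, 0 and 0, adjusted p = 0.125), microbe sensing receptors in 14 of 16 (median -0.36, 0 and 0, adjusted p = 0.236) and plasma cell genes in 10 of 11 (median -0.17, 1 and 0, adjusted p = 0.236). In an exact two-sided permutation test, added after the design was fixed, of the list level in GF against the other 9 libraries (220 splits, the smallest p they can give being 0.00455), T cells, monocytes, neurons, type I interferon and immunoglobulin constant regions each gave that p, with an adjusted p of 0.05 over 55 lists, which is not under the threshold.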

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

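The tests of explanations and the splits of the libraries were chosen only after the results they bear on were seen, except those of ribosomal protein genes against length-matched genes and of Wdfy1, Entpd4 and Ide, while the comparison of Donor7 with Donor3 was fixed in advance.

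The effects of the 2 donor groups against GF differed in 2 genes and 19 lists by the test of Donor7 against Donor3. Gclc had a log2 fold change of -1.10 and Creld2 of -0.87. Median log2 fold changes of the lists lower in Donor7 were -0.63 for immunoglobulin constant regions, -1.55 for variable segments, -0.02 for type 3 lymphocytes, -0.34 for mast cells, -0.37 for pineal gland, -0.65 for glucocorticoid targets, -0.10 for ribosomal proteins, -0.19 for histones, -0.62 for endoplasmic reticulum stress and -0.32 for heat shock. Those higher in Donor7 were 0.63 for leptomeningeal cells, 0.13 for junctions, 0.20 for neurons, 0.62 for astrocytes, 0.64 for skeletal muscle, 0.30 for type I interferon, 0.26 for interferon gamma, 0.21 for NF-kB targets and 0.18 for cholesterol synthesis. These calls used a preset correlation, and with an estimated one 1 of the 19 lists passed, endoplasmic reticulum stress, at an adjusted p of 0.0090 by camera.

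Endoplasmic reticulum stress genes were higher in Donor3 than in Donor7. More plasma cells, which secrete antibody, would bring more immunoglobulin than Hspa5. In 2 of the 3 Donor3 libraries the excess of summed immunoglobulin over Donor7 was below that of Hspa5 (-2.13 against 193 and -37.6 against 255 CPM), which argues against them as the main source. Donor3 replicate 2 went the other way (338 against 247 CPM), and the mean was 99.5 against 232 CPM. Igha had 927 to 1759 counts in Donor3 and 127 to 576 in Donor7, and Jchain 159 to 424 and 83 to 147. Counts of Ighm, Igkc and Mzb1 overlapped between the groups, so plasma cells stay open as a part. With the choroid plexus level as a covariate the list's mean level differed by -0.51 (SE 0.05), against -0.49 without it (SE 0.05), which argues against that tissue. The time of day at sampling cannot be told apart from the groups: the circadian list gave an adjusted p of 0.243 by camera with the preset correlation and 0.795 with an estimated one, and clock genes can stand at one level at different times. A response to the microbiome, handling and cage stay open, and none was tested.

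Immune lists were lower in GF, as a pattern that rests on a preset correlation. In macrophage and complement genes GF replicate 1, at -0.03 and -0.12 (centred log2), lay within the range of the SPF libraries (-0.18 to -0.02 and -0.14 to -0.03). With all libraries thinned to the depth of the shallowest, the mean level of the 7 immunoglobulin genes still tested differed in GF by -2.06 (SE 0.43; -2.53, SE 0.51, unthinned) and that of the T cell, monocyte, macrophage, complement and interferon lists by -0.52 (SE 0.08; -0.53, SE 0.10, unthinned), which argues against shallow sequencing. The slope on the 7SL share within all 4 groups predicted a change of 0.080 for immunoglobulins (95% limits -0.86 and 1.02, -1.85 observed) and -0.20 for the 5 lists (-0.36 and -0.04, -0.56 observed), and within the other 3 groups 0.79 and -0.10, which argues against that share for immunoglobulins and, if the relation is linear, as the whole cause in the 5 lists, but a part stays open there, since their mean level was -0.13, -0.54 and -0.58 in GF replicates 1, 2 and 3 at 7SL shares of 10.2%, 13.3% and 16.2%. With the choroid plexus level as a covariate the immunoglobulin difference was -2.02 (SE 0.50), and with the level of bone-forming, neutrophil and granulocyte precursor genes, low in GF replicates 2 and 3, it was -1.98 (SE 0.57), which argues against these tissues, but that of the 5 lists moved from -0.56 to -0.36 (SE 0.10 both times), so bone and marrow content stays open there. Absence of microbes is a hypothesis that remains, and RNA quality beyond depth and the 7SL share, and the 7SL share together with bone content, were not tested.

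Many genes differed between SPF and the donor groups, and a transcript length bias may account for part: genes matched to ribosomal protein genes on exon length and level had a median log2 fold change of 0.32 in Donor3 against SPF, and ribosomal protein genes stood 0.21 above them, too close to the bound of 0.2 set before to decide (SD 0.02). With the trend on exon length removed 822 of the 1526 genes called in Donor3 still passed. Of ribosomal protein genes 50 passed in Donor3 (73 before) and 33 in Donor7 (65 before). Their mean level stood 0.37 and 0.30 above SPF (SE 0.05). Exon length counted all annotated exons of a gene, which can exceed the length of its transcript, and its median was 1754.5 bases for ribosomal protein genes. A bias by transcript length may thus be removed only in part, so length as the whole cause stays open. With the choroid plexus level as a covariate 61 ribosomal protein genes passed in Donor3 and 7 in Donor7. Their mean level still stood 0.55 (SE 0.08) and 0.45 (SE 0.09) above SPF, against 0.54 and 0.44 without it (SE 0.07). This argues against that tissue for ribosomal protein genes. Their calls fell in part because fewer genes passed and the adjusted threshold grew stricter: at the cutoff of the fit without the covariate 50 ribosomal protein genes would have been called in Donor7. The counts over all genes also fell with that covariate, as given above, so choroid plexus content stays open for other genes. For Nnt, Crb1, Mid1 and Vopp1 a strain difference between the SPF mice and the others is a candidate explanation: GF, Donor3 and Donor7 differed by at most 0.27 (log2, Mid1). Of 3 further genes named for C57BL/6 substrains, the smallest log2 difference of SPF from another group was 0.53 (SE 0.13) in Wdfy1, not above the bound of 0.5 by more than its error, 0.08 in Entpd4 and 0.06 in Ide. These 3 genes need not differ between every pair of substrains, so their values do not weigh against strain. Strain, supplier and the SPF microbiome cannot be told apart here, as each may set SPF apart from the other groups.

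Splits of the libraries into other groups gave the following. With 10 splits the share cannot fall under 0.05. For GF against SPF the real split called 14 genes and the highest other 23 (2 of 10 splits as large), and 34 lists against 28 (1 of 10). For Donor3 against GF they were 0 genes and 4 (10 of 10) and 31 lists and 25 (1 of 10). For Donor7 against GF they were 0 genes and 0 (10 of 10) and 26 lists and 29 (2 of 10). For Donor7 against Donor3 they were 2 genes and 30 (2 of 10) and 19 lists and 25 (4 of 10), and the split with 30 genes joined Donor7 replicate 2 with Donor3 replicates 1 and 2, which points to a structure among these libraries. For Donor3 against SPF they were 1526 genes and 98 (1 of 10) and 15 lists and 28 (7 of 10), and for Donor7 against SPF 1514 genes and 2 (1 of 10) and 21 lists and 24 (3 of 10). Other splits called a median of 14 to 21 lists, so a count of lists says little by itself. For GF against the other groups, 14 of 100 splits called as many genes as the real 1, the highest 149, so chance is not excluded there, and a split that calls so many points to a structure among the libraries, which was not tested. For any difference only the real split, 1 of 100, called as many as 739, and the highest other called 19. That share of 0.01 is the smallest that 100 splits can give. Chance is thus an unlikely source of the count if the libraries are independent, which the labels do not state. The count also rests on single libraries, as it was 7 without SPF replicate 1. For the lists of GF against the other groups 2 of 100 called as many as the real 33, the highest other also 33, but no list passed with an estimated correlation or by the exact permutation test, where the smallest adjusted p was 0.05, so nothing more rests on that count.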

How the results depend on the processing

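No named gene that passed in either fit reversed its direction; 48 values of genes past in neither changed sign. A fit with sex was not run because all libraries had 1 sex pattern. Some choices here were added after seeing the data and are named as such. Counts under alternatives fixed in advance, where they moved by over 1.5 times, were as follows, and the cause was not tested unless named. GF against SPF called 14 genes, 32 without a filter, 2 with only the groups compared, 537 by DESeq2 and 8 by voom. Donor3 against GF called 0, 1 without a filter, 1 with only the groups compared and 325 by DESeq2. Donor7 against GF called 0, 5 without a filter and 478 by DESeq2. Donor7 against Donor3 called 2, 31 without a filter, 1 with only the groups compared, 206 by DESeq2 and 85 by voom. Donor3 against SPF called 1526, 582 with only the groups compared, 2359 by DESeq2 and 3420 by voom, and Donor7 against SPF 1514, 2517 and 3961 by the last 2 tools. GF against the mean of the others called 1, 2 without a filter, 102 by DESeq2 and 0 by limma on normalized values. The test of any difference called 739, 3172 by DESeq2, 3452 by voom and 466 by limma on normalized values. With an estimated correlation, the lists past the threshold fell to 0 of 34 for GF against SPF, 1 of 31 and 0 of 26 for Donor3 and Donor7 against GF, 1 of 19 for Donor7 against Donor3, 1 of 15 and 0 of 21 for Donor3 and Donor7 against SPF, and 0 of 33 for GF against the mean.

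The labels number replicates alike in all groups, and whether the numbers pair the libraries stays open. Of same-numbered pairs, 5 of 18 had deviations correlated over 0.1 (range -0.151 to 0.257), and 6 of 12 libraries correlated best with their own number. The mean correlation was 0.020 for same-numbered pairs and -0.010 for other pairs, too close to show or exclude pairing. With the replicate number as a block, GF against SPF called 7 genes, Donor7 against GF 2, Donor7 against Donor3 13, GF against the mean 0 and any difference 174.

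Alternatives chosen after seeing the data came next. Without GF replicates 2 and 3, which leaves 1 GF library assumed to vary like the others, GF against SPF called 9 genes and 20 lists, GF against the mean 3 genes and 20 lists, and Donor3 and Donor7 against GF 18 lists each. With the choroid plexus level as a covariate GF against SPF called 2 genes, Donor3 and Donor7 against SPF 414 and 84, GF against the mean 0 and any difference 22. With the length trend removed Donor3 against SPF called 926 and any difference 357. The direction of the list test turned in 8 cases. Without GF replicates 2 and 3 the medians then were -0.00353 for border macrophages in GF against SPF, -0.0264 for mitochondrially encoded genes and -0.00569 for histones in Donor3 against GF, and -0.0297 for blood endothelium and -0.190 for aryl hydrocarbon receptor targets in GF against the mean; those of macrophages and aryl hydrocarbon receptor targets kept their sign. Blood endothelium ran from -0.0233 without GF replicate 3 to 0.128 without GF replicate 2. With the covariate, cell division in GF against SPF was 0.0931 and oxidative phosphorylation in GF against the mean -0.0137.

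Leaving out 1 library gave 3 (without GF replicate 3) to 13 genes and 22 to 36 lists for GF against SPF, 0 to 147 (without GF replicate 1) and 27 to 33 lists for Donor3 against GF, 0 to 875 (without GF replicate 1) and 24 to 31 lists for Donor7 against GF, 1 to 11 and 18 to 25 lists for Donor7 against Donor3, 74 (without SPF replicate 1) to 1869 and 14 to 18 lists for Donor3 against SPF, 10 (without SPF replicate 1) to 1838 and 18 to 22 lists for Donor7 against SPF, 0 to 22 and 30 to 34 lists for GF against the mean, and 7 (without SPF replicate 1) to 1966 (without GF replicate 1) genes for any difference. The total of 7026082 counts in GF replicate 2 limits what can be called for rare transcripts such as immunoglobulin segments.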

Other observations

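The permutation test used in this part was added after the design was fixed, and the lists were fixed in advance. SPF differed from the other 9 libraries in 7 lists by the exact two-sided permutation test of list levels (220 splits, p = 0.00455, the smallest they can give). The adjusted p of this test was 0.0357 over the 55 lists of SPF alone, and it rests on 7 lists tied at the smallest p. The test was run on each of the 4 groups with no adjustment over the groups, so these calls are weak. B cell genes averaged 0.29 ± 0.04 in SPF and -0.10 ± 0.17 elsewhere on the centred log2 scale, and genes of type 2 lymphocytes 0.23 ± 0.03 and -0.08 ± 0.12, each in the same direction in 3 of 3 SPF libraries. Lower in SPF were oxidative phosphorylation genes of the nucleus, at -0.25 ± 0.18 against 0.08 ± 0.08, ribosomal proteins, at -0.32 ± 0.11 against 0.11 ± 0.12, mitochondrially encoded genes, at -0.46 ± 0.11 against 0.15 ± 0.18, histones, at -0.36 ± 0.26 against 0.12 ± 0.21, and fatty acid oxidation genes, at -0.23 ± 0.01 against 0.08 ± 0.12. Genes with exon lengths near 500 bases were low in SPF as well. The small noncoding RNAs Rny1, Rny3, Snord21 and Snord49b went the other way, being lower in Donor3 than in SPF. At 500 bases the trend of log2 level on exon length was -0.25, -0.06 and -0.12 in SPF replicates 1, 2 and 3. That trend was -0.02 to 0.18 in the other 9 libraries. The choroid plexus level was -2.75, 0.05 and -1.89 in these SPF replicates, where that of oxidative phosphorylation genes was -0.40, -0.05 and -0.30, while Donor3 replicate 3, at a choroid plexus level of -2.31, had -0.04.

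In Donor3, by the same exact permutation test, endoplasmic reticulum stress genes averaged 0.41 ± 0.04 against -0.14 ± 0.08 in the other 9 libraries and heat shock genes 0.30 ± 0.20 against -0.10 ± 0.11, each at the smallest p of 0.00455 with an adjusted p of 0.125. In Donor7 type I interferon genes averaged 0.27 ± 0.09 against -0.09 ± 0.17, with an exact permutation p = 0.00909 and an adjusted p of 0.25. None of these passed.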
